A study of Drosophila melanogaster with 2 samples.

How the data were processed

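Chromatin immunoprecipitation with sequencing was done by the authors on whole embryos of flies with an Oaz-eGFP fusion, 0 to 24 hours old, with an anti-GFP antibody and sonicated fragments of 200 to 800 bp, per the labels. There were 2 biological replicates in 1 group. The labels give both Oaz and GFP for the antibody, in different fields. The aligner and peak caller are not given in the sources used here. Per the description deposited with the samples, the lists of the series came from the alignments of both replicates and a control, and the lists of a sample from the alignments of 1 replicate and the control, on dm6. Control reads, raw reads and coverage were not analysed here.

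The 8 peak lists were 4 thresholded and 4 ranked lists: optimal and conservative lists for both replicates together, and a list for each replicate. Each peak has a deposited signal value from the authors' peak caller, on a scale that the sources do not state. The ranked lists also have the deposited −log10 of the global IDR, a measure of how far peaks rank alike in repeated measurements. All listed peaks had an IDR of 0.01 or less. Per-library signal columns in the ranked lists (8 columns) were not used here. Signals were compared as deposited, with no further normalization. The signal of a list made from both replicates is not on the scale of a single replicate.

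The reference genome was Release 6, whose arm lengths held every listed arm peak, with 0 peaks past an arm end. Genes came from Ensembl release 115, with 13968 protein-coding genes and 19630 protein-coding TSSs on the arms. Symbols of the gene lists were matched through synonyms, and 5 symbols were not matched. Peaks on unplaced contigs were left out of the comparisons. Coordinates are 1-based on dm6.

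The gene lists (28), the motifs (23), the tests, the choice of named genes and most alternatives were fixed before the data were examined. Named were Oaz, the 20 strongest optimal-list peaks shared by both replicate lists, by the nearest protein-coding TSS and any host gene, up to 4 members with the strongest peaks of each list past its test and of 5 lists chosen for Oaz, and the 3 highest and 3 lowest motifs past the test. The 6-mers named, the housekeeping families and the position of ACAGTG were chosen after the values were seen, as were the Polycomb, heat shock, EGFR, Hox, pair-rule and neuroblast lists given beside their counts.

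Overlap of replicates was 1 bp or more, set against 1000 circular shifts within each arm. Location used an order of promoter (500 bp to either side of a TSS), 5' UTR, CDS, 3' UTR, intron and intergenic, set against 1000 uniform placements on the same arm, two-sided. Gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests on genes with a summit within 1000 bp of a TSS. Motifs and 6-mers on either strand were counted in windows of 201 bp at summits and 700 bp to the left and right, with a two-sided exact McNemar test against 1 flank drawn at random. The printed flank share is the mean of both flanks, and folds have 1 window added to both sides. The X share had an exact binomial test, and the 693 strongest and 693 weakest peaks by signal had Fisher's exact tests. Adjusted p values follow Benjamini and Hochberg within each family, and the threshold was 0.05. Intervals are Wilson 95% intervals unless named otherwise.

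The tests were tested on simulated data. In 10 sets of evenly placed peaks, 1 of 60 location classes, 1 of 280 lists and 0 of 230 motifs were called. Evenly placed peaks, unlike the real ones, favour neither TSSs nor a base composition at summits. Their rate of false calls therefore need not hold for the gene list and motif tests here. With planted effects, a promoter share of 48.1% was recovered as 47.4% over 2772 peaks, 5 of 5 planted gene lists were called over 13968 genes with 1 other list, a planted M1BP share of 9.99% was recovered as 10.1% over 2772 peaks with 1 other motif called, the strongest planted 6-mer ranked 1 over 2772 peaks, and a replicate overlap of 70.5% was recovered as 72.4% over 2772 peaks.

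Alternatives changed the peak list, the IDR threshold (0.001), overlapping peaks, the replicate used, promoter and motif windows, the assignment of peaks to genes, the test and the background. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, with random seed 7.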

Results

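Binding of the zinc-finger protein Oaz was mapped by chromatin immunoprecipitation and sequencing in whole Drosophila melanogaster embryos aged 0 to 24 hours. The flies carried Oaz fused to eGFP, and the antibody was directed against GFP. There was 1 group, with 2 biological replicates and no second condition, so the comparisons below set peaks against chance placement, flanking sequence, gene groups and each other. The authors' optimal list held 2846 peaks, the conservative list 2524, the list of replicate 1 held 1833 and that of replicate 2 held 1680. The optimal list was 1.13 times as long as the conservative list, and the list of replicate 1 was 1.09 times as long as that of replicate 2. Peaks on the chromosome arms numbered 2772 in the optimal list, and all values below are for these unless another list is named. Median peak width was 330 bp in the optimal list and 304 bp in each replicate list. With a global irreproducible discovery rate (IDR) of 0.001 or less in place of 0.01, 1300 peaks remained. Read counts were not analysed here, so the depth behind the peaks is unknown, and the 95% intervals (Wilson) cover counting error over peaks or genes only.

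The Oaz gene itself lay in a dense cluster of peaks. The gene, listed under the symbol L (FBgn0288433), spans 2R 14435899 to 14465881 on the plus strand of dm6. The gene and 20 kb to each side held 16 peaks, of which 9 lay in the gene body, 4 upstream and 3 downstream. Windows of the same width held 1.41 peaks on average. The strongest peak of the locus, at 2R 14435590 to 14435741, had its summit 237 bp upstream of the gene start, a signal of 298 and rank 239 among all 2846 listed peaks. A peak at 2R 14484522 to 14484851, downstream of the gene, had a signal of 282. Of 13709 windows of this width, the only 2 with as many peaks start at 2R 14420000 and 14430000 and overlap this locus. The count was 12 in the conservative list, 9 in that of replicate 1 and 6 in that of replicate 2, and it was 5 at an IDR of 0.001 or less. Windows with as many peaks as the locus had in the same list numbered 5 for the conservative list, 16 for replicate 1 and 139 for replicate 2. The count of peaks was not tested, and the flies are transgenic for an Oaz fusion, which can add copies of the locus.

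**Figure D1:**
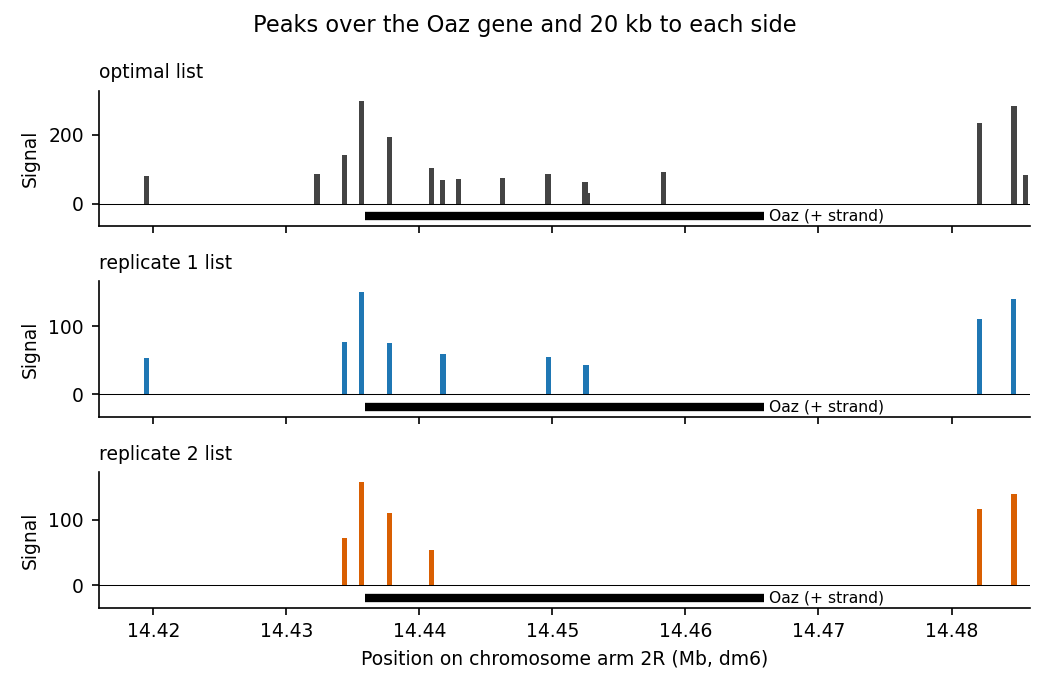
Peak signal (authors' scale, linear axis) against position on 2R (Mb, dm6) over Oaz and 20 kb to each side, with 1 bar per peak in the optimal list and in each replicate list and the gene as a black bar. The optimal list has 16 peaks here, the list of replicate 1 has 9 and that of replicate 2 has 6.

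Most peaks of either replicate were found in the other. Of the 1759 arm peaks of replicate 1, 1248 (70.9%, 68.8 to 73.0) overlapped a peak of replicate 2, where circular shifts of the list gave 0.694%. Of the 1670 arm peaks of replicate 2, 1264 (75.7%, 73.6 to 77.7) overlapped a peak of replicate 1, against 0.745% by shifts. The one-sided permutation p was 0.001 in both directions, the smallest that 1000 shifts can give. Shared peaks of replicate 1 had a median signal of 97.8, and its unshared peaks one of 56.4. In replicate 2 these medians were 74.1 and 46.4. Of the unshared peaks, 90.8% in replicate 1 and 85.2% in replicate 2 overlapped a peak in the other replicate's longer ranked list, where shifts gave 31.9% and 48.4%.

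Peak strength in the optimal list was compared between replicates over the 1260 peaks (45.5%) that both replicate lists contained. Across these peaks, which are not independent replicates, Spearman's rho was 0.819 (bootstrap 95% interval 0.794 to 0.842), and Pearson's r of the log2 signals was 0.889. The optimal list held 119 overlapping pairs of peaks, and such a pair can take its values from the same replicate peaks. Some points behind these correlations and the interval are therefore repeated. The median log2 ratio of replicate 1 to replicate 2 was 0.36 (SD 0.36 across peaks). A further 752 optimal peaks were in 1 replicate list and 760 in neither. Over the 63819 peaks, out of 150275 ranked ones, that lay on the main arms and overlapped a ranked peak of both replicates, most of them past no threshold, rho was 0.299.

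**Figure D2:**
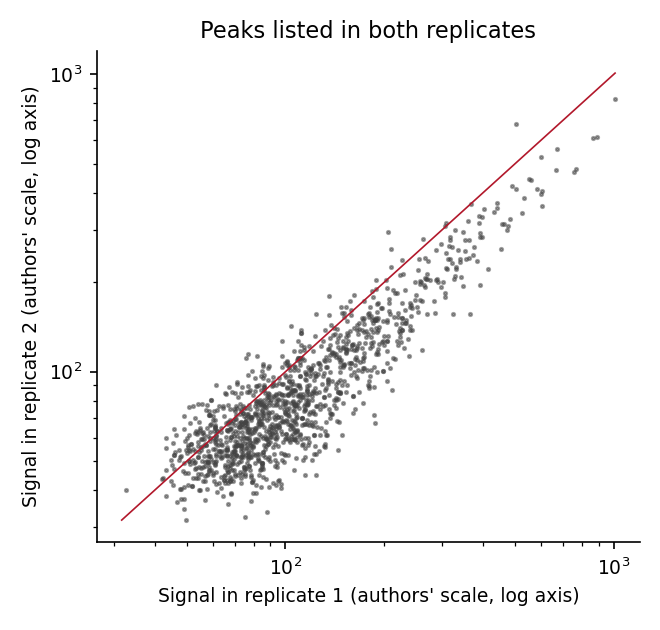
Signal in replicate 1 (horizontal) against signal in replicate 2 (vertical), both on the authors' scale and log axes, with 1 point per optimal-list peak present in both replicate lists and a line at equal signal. The 1260 points, some of which coincide, rise together (rho 0.819) and lie mostly below the line.

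Most of the strongest peaks lay next to gene start sites. The 20 peaks with the largest signal that both replicates shared had signals from 811 to 1849, and 14 of them lay in promoters, 3 in introns and 3 between genes. Their summits lay within 150 bp of a transcription start site (TSS) at 13 of the 20. The strongest peak, at 2L 6612545 to 6612885 in an intron of CG11050 (FBgn0031836), had a signal of 1849, with 1009 in replicate 1 and 828 in replicate 2. The next, at 3L 19590471 to 19590751, lay 94 bp from the TSS of CG14100 (FBgn0036889) and had a signal of 1501.

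Genes for mitochondrial ribosomal proteins were named by 2 of these peaks. One, at 2R 15217606 to 15217902, lay 143 bp from the TSS of mRpL41 (FBgn0034001), with signals of 864 and 609 in replicates 1 and 2. The other, at 3R 15229394 to 15229668, lay 128 bp from the TSS of mRpS10 (FBgn0038307), with signals of 600 and 528. PNPase, a mitochondrial RNA-degrading enzyme, had a promoter peak of signal 1008 at 3R 31404529 to 31404784. The peak at 2R 21703179 to 21703626 lay in introns of HmgZ and HmgD, which encode high-mobility-group DNA-binding proteins, with a signal of 1266. Ugalt, a UDP-galactose transporter, had a promoter peak of signal 1221 at X 2703742 to 2704019.

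Chromatin proteins were also among the named genes. The promoter peak of ph-p (FBgn0004861), a Polycomb-group gene, lay at X 2137217 to 2137485 with signals of 665 and 476 in replicates 1 and 2. RYBP, whose product binds Polycomb complexes, had the nearest TSS to a peak of signal 1196 between genes at 2R 22678169 to 22678612, 7622 bp away. Chro, which encodes a chromodomain protein, had a promoter peak of signal 913 at 3L 22878772 to 22879028. The remaining peaks were named CG7601, CenG1A, CG5611, eIF6, CG18549, Tcs5, CG13323, CG4004, CG13390 and CG32772, with signals from 811 to 1212. The peak named eIF6, a ribosome biogenesis factor, also lies in the gene ytr. The nearest gene names a peak and is not shown to be regulated by it.

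Peaks were concentrated at promoters and sparse in coding sequence. Summits within 500 bp of a protein-coding TSS made up 44.1% (1223 of 2772, 42.3 to 46.0), which was 3.84 times the 11.5% given by random placement on the same arm. The share was 49.01% in the list of replicate 1 and 50.4% in that of replicate 2. Coding sequence held 1.70% of summits against 13.9% by placement, 3' UTRs 0.794% against 4.52%, and intergenic sequence 16.2% against 30.02%. The adjusted permutation p was 0.0015 for each of these 4 classes, at the smallest raw p of 0.001 that 1000 placements can give. Introns held 36.7% against 39.3% (adjusted permutation p 0.012), and 5' UTRs 0.505% against 0.797% (adjusted permutation p 0.0889). Each summit has a single class, so the promoter excess lowers the shares of all other classes. The intron share among summits outside promoters was not tested, so the value is no sign that such summits avoid introns. With promoters limited to 250 bp, the intron share was 41.4% and no longer below chance (adjusted permutation p 0.505). Against ranked summits outside the list as background, the intron call ended (adjusted permutation p 0.135) and 5' UTRs passed (adjusted permutation p 0.036), as they did in the conservative list (adjusted permutation p 0.014).

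**Figure D3:**
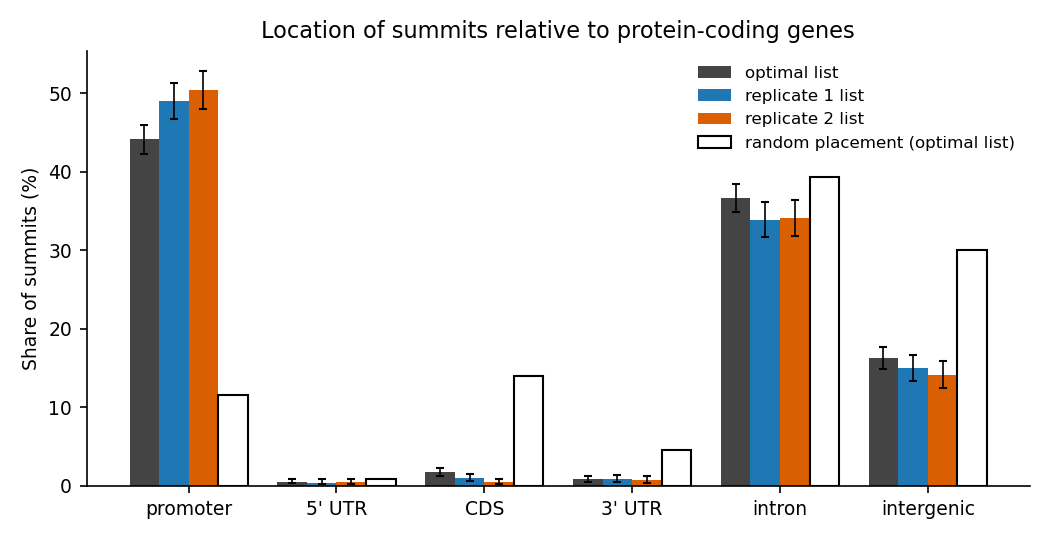
Share of summits (%) in each class of location for the optimal list and each replicate list (filled bars, Wilson 95% intervals), beside the mean of 1000 random placements of the optimal list (open bars). Promoters hold 44.1% of optimal-list summits against 11.5% by placement.

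Stronger peaks lay at promoters more often than weaker ones. Among the 693 peaks with the highest signal, 411 summits (59.3%, 55.6 to 62.9) lay in promoters, against 206 (29.7%, 26.4 to 33.2) among the 693 with the lowest (two-sided Fisher's exact p 1.09e-28). Near TSSs of genes in the fixed lists the shares were 3.75% and 2.45% (Fisher's exact p 0.215). Their direction turned in 4 of 8 alternatives, and 1 other, with the list split at its median signal, passed the threshold (4.91% against 3.32%, Fisher's exact p 0.0441). Some of the weakest peaks overlapped a much stronger peak, such as 1 on 2L with a signal of 8.30 beside 143. Neither comparison was repeated with only the strongest of overlapping peaks.

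The X chromosome held slightly more peaks than its length gives. X carried 535 of the 2772 peaks (19.3%, 17.9 to 20.8), against 17.1% of the arm length (two-sided exact binomial p 0.00268). The density was 22.7 peaks per Mb on X, 22.5 on 2L, 21.6 on 2R, 19.9 on 3L and 18.6 on 3R. Chromosome 4 had 2.97 peaks per Mb and Y 0.818. Peaks on contigs named as parts of X were not counted. The share on X was 20.5% in the list of replicate 1 and 20.4% in that of replicate 2.

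Genes for cytoplasmic ribosomal proteins had peaks at their start sites far more often than other genes. A summit lay within 1000 bp of a TSS at 50 of 85 ribosomal protein genes (58.8%, 48.2 to 68.7), against 13.7% of other protein-coding genes (adjusted Fisher's exact p 1.67e-20). The peak of RpL32 (FBgn0002626) at 3R 30046251 to 30046383 had a signal of 341, with 192 in replicate 1 and 152 in replicate 2. Those of RpS27 at 3R 25247435 to 25247587 and RpL7 at 2L 10200975 to 10201117 had signals of 312 and 305. The peak of RpL14, at 3L 8600875 to 8601017, had a signal of 261. Circular shifts of the peaks, which keep the spacing of peaks and genes, were tested in 3 forms. The call was made with equal tails of the log ratio (adjusted permutation p 0.0112), a form chosen after the deviation of the log ratio was seen. That value came from the smallest raw p of this form, tied with lists without a summit, among them Hox, pair-rule and neuroblast genes. Those lists reach it for a reason given below, and without such ties the adjusted value would not have passed. The call was also made with the absolute deviation of the count of genes (adjusted permutation p 0.00699). The count form does not divide by other genes, so the general concentration of peaks at promoters raises it too. Its call is therefore no support for an enrichment particular to ribosomal protein genes. The call ended with the absolute deviation of the log ratio (adjusted permutation p 0.164).

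Sensory receptor and cuticle genes had fewer peaks than other genes. Odorant receptors and gustatory receptors each had a summit at 1 of 60 genes (1.67%, 0.295 to 8.86; adjusted Fisher's exact p 0.016 for each). The odorant receptor gene was Or88a, with a signal of 161 at 3R 14108631 to 14108960, and the gustatory one was Gr32a, with a signal of 58.1 at 2L 11113062 to 11113391. Genes for cuticle proteins had a summit at 2 of 70 (2.86%, adjusted Fisher's exact p 0.0264), which were Cpr73D and Cpr65Eb. With circular shifts (equal tails) these 3 calls ended (adjusted permutation p 0.177, 0.184 and 0.516), and the odorant receptor call also ended in each replicate's list (adjusted Fisher's exact p 0.111 and 0.114). The odorant and gustatory calls ended at an IDR of 0.001 (adjusted Fisher's exact p 0.314 and 0.0658), and the cuticle call in the list of replicate 2 alone (adjusted Fisher's exact p 0.0613). Replication-dependent histone genes had a summit at 0 of 111 (upper limit 3.35%, adjusted Fisher's exact p 1.45e-06). Among genes with a ranked peak the list kept 15 genes, 0 with a summit (log2 odds -2.50), too few for the call (adjusted Fisher's exact p 0.464). The call also ended with circular shifts of the count of genes (adjusted permutation p 0.64). Histone genes lie in tandem copies of nearly the same sequence. Fisher's exact test and the upper limit treat these neighbours as independent genes, so both overstate the certainty. How reads were placed there was not tested.

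The lists for Dpp signalling, the posterior spiracle and the trachea did not pass within 1000 bp of a TSS. In the Dpp/BMP pathway, which patterns the embryo through a secreted growth factor, 2 of 21 genes had a summit (9.52%), namely Mad (signal 169, 2L 3153211 to 3153540) and brk (signal 124, X 7307000 to 7307329). Among Dpp target genes the count was 2 of 19, brk and ush. The posterior spiracle list had 3 of 14, namely Cad96Ca, crb and shg, and the tracheal list 2 of 13, sty and bnl. Their adjusted Fisher's exact p values were 0.923, 1, 0.923 and 0.923. When each peak was given to its nearest TSS at any distance, the Dpp/BMP list passed (38.1%, adjusted Fisher's exact p 0.0296), as did the posterior spiracle list (6 of 14, 42.9%, adjusted Fisher's exact p 0.0296). With circular shifts under this assignment neither passed (adjusted permutation p 0.583 and 0.997). Over its alternatives the adjusted p of the Dpp/BMP list, by Fisher's exact or permutation tests, ran from 0.0181 to 1.

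Polycomb and Trithorax genes (6 of 15), heat shock genes (6 of 16) and EGFR pathway genes (5 of 13) had summits at 40.0%, 37.5% and 38.5% of members. None of these passed (adjusted Fisher's exact p 0.0555, 0.0673 and 0.0899). The Polycomb and Trithorax call was made in 8 of 17 alternatives, the heat shock call in 6 and the EGFR call in 4. Over these alternatives the adjusted p by Fisher's exact or permutation tests ran from 0.000636 to 0.563, from 0.00699 to 0.563 and from 0.000972 to 0.933. Hox, pair-rule and neuroblast genes had no summit at 8, 10 and 19 members, which allows shares of up to 32.4%, 27.8% and 16.8% (adjusted Fisher's exact p 0.923, 0.923 and 0.301). With circular shifts (equal tails) all 3 lists were lower (adjusted permutation p 0.0112 for each), but this says nothing about their genes. The form divides by the share of other genes, which shifts lower by moving peaks off promoters. A list with no summit then lies below even a shift that also leaves it with none. With the nearest TSS the shares of the 3 lists, 37.5%, 30% and 15.8%, were above those of other genes and past no threshold. Over all 28 lists, 1 was higher and 4 were lower after adjustment, and 8 had an unadjusted Fisher's exact p under 0.05.

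**Figure D4:**
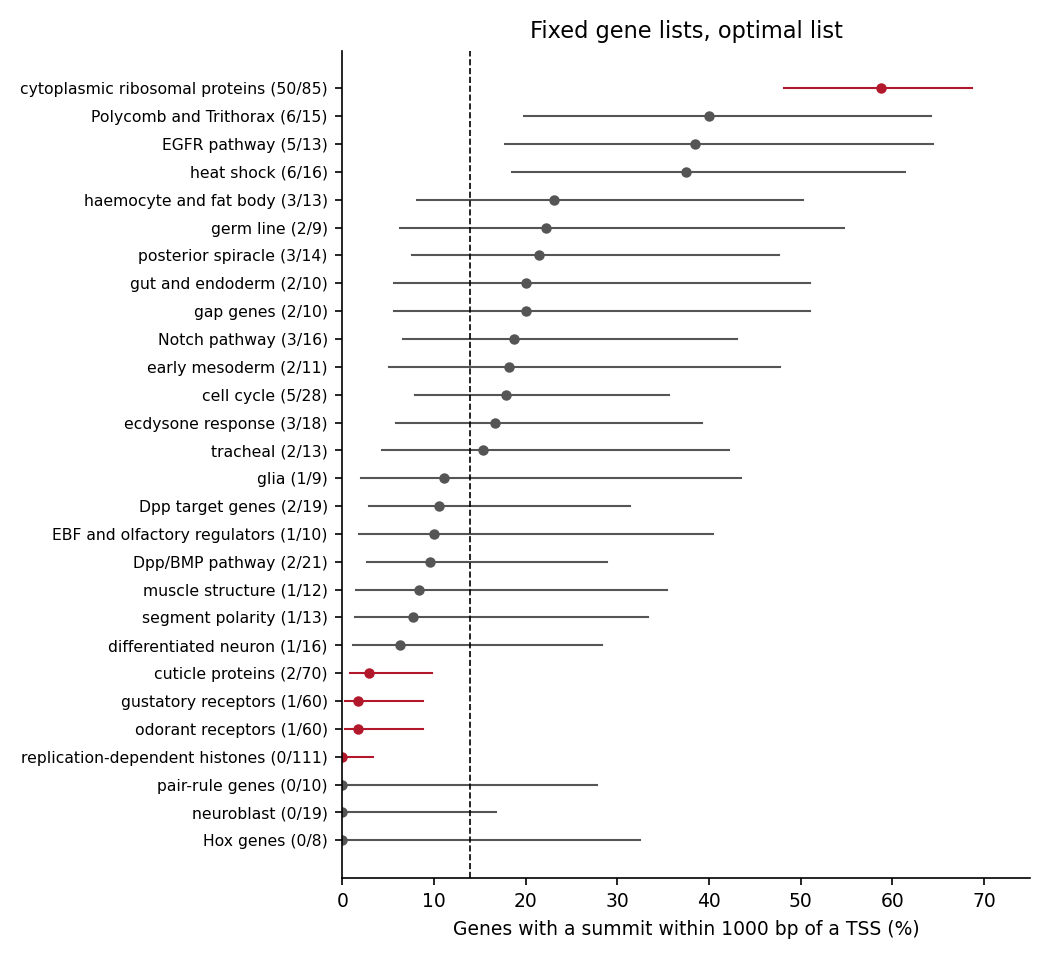
Share of genes (%) with an optimal-list summit within 1000 bp of a TSS in each of 28 fixed gene lists, with Wilson 95% intervals, counts in brackets and a dashed line at the share of all protein-coding genes (13.96%). Red marks the 5 lists past the adjusted threshold of 0.05, with ribosomal protein genes at 58.8%.

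Core promoter sequences were among those more frequent at summits than in flanking sequence. The DNA replication-related element TATCGATA was in 2.78% of summit windows against 0.541% of flanks (4.88-fold, adjusted exact McNemar p 1.11e-09). The M1BP site GGTCACACT was in 1.01% against 0.397% (2.42-fold, adjusted exact p 0.0382), and the TATA box in 35.3% against 20.6% (1.71-fold, adjusted exact p 1.77e-30). Lower than flanks were the EBF core (0.866% against 1.64%, adjusted exact p 0.0161), the CA repeat (3.21% against 5.81%, adjusted exact p 8.76e-06) and the GC box (4.87% against 8.12%, adjusted exact p 9.76e-06). Of 23 motifs, 6 were higher and 4 lower. The site GCACCC described for vertebrate relatives of Oaz was in 4.26% against 5.66% (adjusted exact p 0.198). It was lower in the list of replicate 2 (3.29% against 5.51%, adjusted exact p 0.0132) and not called in that of replicate 1 (adjusted exact p 0.274) or the conservative list (adjusted exact p 0.0564). Against sequence at the same distance from the TSS of genes without a peak, the DRE call ended (2.78% against 2.11%, adjusted p 0.393 by an exact test) and M1BP turned (1.01% against 1.17%), and 4 of the 10 calls were made, the TATA box among them. The TATA box call was also made at summits over 1000 bp from a TSS, so it is not particular to promoters. Against shuffled summit windows CA repeat and GC box turned, and the EBF core call ended in 7 of 12 alternatives.

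AT-rich 6-mers and ACAGTG were the most enriched at summits. By p, AAAATA led with 55.2% of windows against 33.5% of flanks (1.65-fold, adjusted exact p 3.73e-49), and ACAGTG was the fifth. By fold ACAGTG was the highest of all 6-mers. It was in 615 of 2772 summit windows (22.2%) against 8.64% of flanks, 2.56-fold (adjusted exact p 2.97e-40). Of 6-mers with 3 or more G or C, the next by fold were ACACTG and ACTGTG, at 2.09-fold and 1.96-fold (adjusted exact p 4.77e-21 and 8.16e-15). Of 2080 6-mers, 413 were higher and 787 lower, along with a GC content of 37.0% at summits and 42.8% in flanks. The 6-mers CTCCTC, CGAGGA and GGAGGA were lower, at 0.332, 0.321 and 0.339 times the flanks. Beyond 1000 bp from a TSS, 217 6-mers passed, and ACAGTG was in 23.7% of those summits. Summits lay most often 60 to 100 bp to the 3' side of ACAGTG, where each of the 2 bins of 20 bp had 54.5 sites per 1000 peaks, 5.98 times the mean far from summits. In the lists of replicates 1 and 2 the bin from 80 to 100 bp was the highest, at 7.06 and 7.07 times the far mean.

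**Figure D5:**
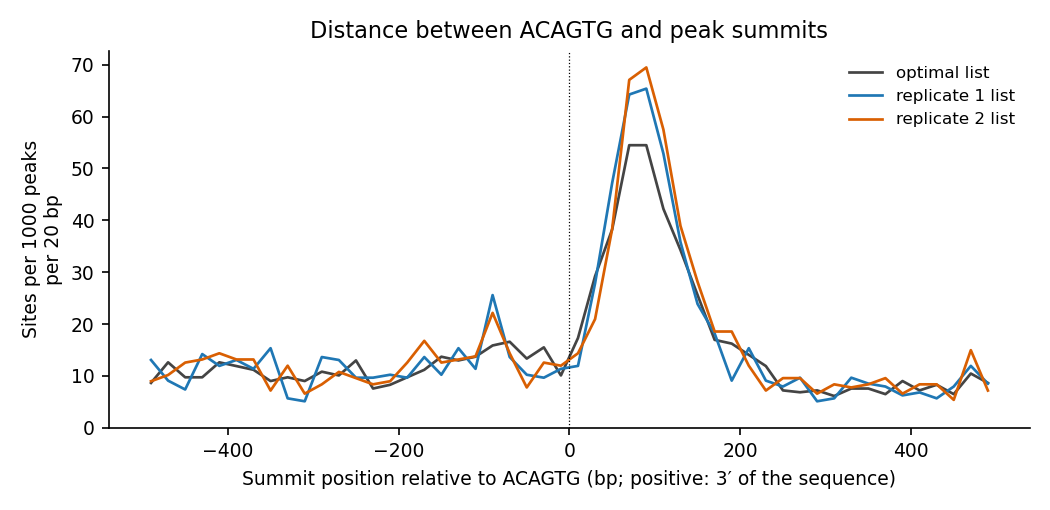
ACAGTG sites per 1000 peaks in bins of 20 bp (vertical) against the position of the summit along the strand of the site (bp, positive to the 3' side), for the optimal list and each replicate list. All 3 lines are highest with the summit 60 to 100 bp to the 3' side, at 54.5 sites per 1000 peaks in the optimal list.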

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

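No test was run on the values in this part. The contig peaks entered only the counts, widths and signals of the lists. Ranked peaks outside the thresholded lists served above only as background, in the overlap of unshared peaks and in correlations over ranked peaks.

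Peaks on contigs outside the chromosome arms drew attention because the comparisons of location, genes and sequence leave them out. The optimal list held 74 of them on 60 contigs, all named as parts of X, and the conservative list held 29. The list of replicate 1 held 74 and that of replicate 2 held 10, which is 4.04% and 0.595% of each list. The strongest in the optimal list had a signal of 612 and rank 48.

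Ranked peaks with an IDR of 0.01 or less that the thresholded lists do not hold also drew attention. There were 155 for the optimal list, 92 for the conservative list, 172 for replicate 1 and 56 for replicate 2. Of the 155, 109 lay on the arms, among them 47 on 3R, and 46 on contigs. The strongest had a signal of 1442, beside 1849 for the strongest listed peak.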

How the results depend on the processing

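Alternatives with an IDR of 0.001, with ranked summits as the location background, without Y, with the strongest of overlapping peaks, with genes without a peak as background, for 6-mers and the Oaz locus, for optimal peaks against each replicate's ranked peaks, and those joining an assignment of genes to circular shifts were chosen after the data were seen. So were the forms of the shift test, the equal-tailed one after an absolute deviation of the log ratio had ended the ribosomal protein call. No paired analysis was possible because there was a single group. An IDR limit of 0.01 removed no peak and is left out of the total that follows. Counts of alternatives given for single results include it. Of 503 other values under alternatives, 378 kept direction and side of the threshold or, for counts, stayed within 1.5 times, while 45 were weaker, 30 stronger, 38 reversed and 12 moved. A count does not say which lists passed: with circular shifts 5 passed, of which 2 were among the 5 of the main test. These 2 were the ribosomal protein and histone lists. The Hox, pair-rule, neuroblast and histone lists, none with a summit, passed with shifts for the reason given above. The histone pass is therefore no agreement with the main test. The promoter share (35.2% to 54.7%), the X share (19.3% to 21.6%), ACAGTG (22.2% to 24.2%) and both replicate overlaps (64.1% to 78.1% and 68.1% to 82.3%) kept their calls in every alternative run. The ribosomal protein share (41.2% to 60.98%) kept its call in 16 of 17, all but the shift form named above. Unknown read depth limits what weak peaks can show.

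Where no reason is given, the cause was not tested. At an IDR of 0.001, 1300 peaks were listed, 5 of them at Oaz, the posterior spiracle share was 0%, and Dpp/BMP stayed at 9.52% while that of other genes fell, which turned its direction; the same 9.52% turned with the stronger part of the list. Without 1 replicate, the Oaz count was 6 to 9, Dpp/BMP was 9.52% in both lists, still below other genes (10.1% and 9.57%) with only the corrected log2 odds turned (0.19 and 0.28), and the top minus bottom difference for listed genes was -0.911 to -0.480 points. That difference was -2.31 in the stronger part of the list and -2.51 at an IDR of 0.001. Signal rho was 0.299 over the 63819 ranked peaks, and 0.738 over the 2682 optimal peaks, that overlapped a ranked peak of both replicates.

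With the nearest TSS, 10 lists passed, Dpp/BMP was 38.1%, Dpp targets 31.6%, Hox 37.5%, pair-rule 30% and neuroblast 15.8%, all turned to above other genes. With the gene body or 1000 bp upstream, 9 lists passed, Dpp/BMP was 42.9% and Dpp targets 26.3%. With circular shifts added, the ratio of the Dpp/BMP share (38.1% by nearest TSS, 42.9% by gene body) to that of other genes stayed above its shifts, past no threshold. In the gene body form 3 lists passed, and the ratio of the posterior spiracle share (35.7%) to that of other genes was below its shifts. For tracheal genes the ratio of their share to that of other genes turned to below its shifts, while the share itself was not compared. This held with shifts alone (equal tails or absolute log ratio, share 15.4%) and with shifts under both assignments (share 23.1%). With shifts of the count of genes, which do not divide by other genes, Dpp/BMP at 9.52% and Dpp targets at 10.5% turned to above the shifts. At 500 bp from a TSS, posterior spiracle was 7.14% and tracheal 7.69%. The intron share was 41.4% with a promoter of 250 bp.

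With shuffled summit windows as background, CACCTG (5.48%), GATA (27.9%), homeodomain (16.8%), CA repeat (3.21%) and GC box (4.87%) turned. Beyond 1000 bp from a TSS, 1 motif (the TATA box) and 217 6-mers passed, with CGATA at 19.98% and M1BP at 0.0796%, on fewer summits. Against genes without a peak, 4 motifs passed, with CGATA at 26.2%, M1BP at 1.01% and CA repeat at 3.21% on the other side of their background.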

Other observations

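The tests of distal summits, the peak caller, inward pairs, repeat copies and tRNA genes were chosen after the result was seen, and the 5 housekeeping families after the named peaks were seen.

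Other housekeeping families had peaks at smaller shares than the ribosomal protein genes. A summit lay within 1000 bp of a TSS at 12 of 73 mitochondrial ribosomal protein genes, 7 of 33 aminoacyl-tRNA synthetase genes, 7 of 34 complex I genes, 8 of 44 translation initiation factor genes and 2 of 32 proteasome genes. None passed Fisher's exact test after adjustment (adjusted p 0.482 to 0.5), and none had an unadjusted p under 0.05 (0.212 to 0.5). The strongest synthetase peak was that of GluProRS, with a signal of 316 at 3R 23958475 to 23958626. The strongest complex I and proteasome peaks had signals of 299 (ND-ASHI) and 147 (Rpn3). These lay below the strongest ribosomal protein peak (RpL32, 341). Above it were the strongest peaks of mitochondrial ribosomal protein genes (mRpL41, 1467) and of initiation factor genes (eIF2Bbeta, 1221).

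ACAGTG was also more frequent among the 693 strongest peaks (26.6%, 23.4 to 29.96) than among the 693 weakest (18.9%, 16.2 to 21.99, Fisher's exact p 0.000842). Some of the weakest peaks overlapped a stronger peak, and this was not held constant. Summits in promoters held it at 20.2% and those over 1000 bp from a TSS at 23.7% (Fisher's exact p 0.037). Neighbouring bases were counted at 518 sites with the summit on their 3' side, in a distance range chosen after the positions were seen. Of these, 54.8% had G at the second base before the sequence and 60.4% had G just after it. The shares were 24.4% and 35.5% at 513 sites far from summits. These were the largest differences among the bases counted, and they were not tested.

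The first pattern weighed was ACAGTG at summits. Base composition as the whole cause is argued against, since shuffled summit windows held ACAGTG at 7.31% and summits at 22.2%. Promoter sequence in general was argued against by distal summits, which held it at 23.7% against 8.80% of their flanks. For summits 90 to 150 bp from their only site, 4.06% (2.28 to 7.12, n = 271) had a ranked summit at the mirror point across the site. At the control point it was 4.43%. In this range, narrowed after a first result, summits set to both sides of a site by the peak caller are argued against. Ranked summits keep a distance from each other, so summits nearer the site could not be tested this way. What binds ACAGTG was not tested, so its binding by the tagged protein or by a partner is only a hypothesis.

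The position of ACAGTG was tried under 4 further hypotheses. A preference centred on the summit is argued against, because 13.7% of sites lay within 25 bp of it (11.4 to 16.4, n = 715), below the 25.5% of an even spread, a reading settled after the value was seen. A fixed side is consistent with the values, as 67.8% of summits 50 to 150 bp from a single site lay to its 3' side (63.5 to 71.8, n = 481). Of 116 summits with a site on each side, 83.6% (75.8 to 89.3) had both sites pointing at the summit. In flanks it was 51.9% (34.0 to 69.3) of 27 such pairs (Fisher's exact p 0.00133). Random strands would give 25%, but the side bias of single sites alone raises the share above that. Whether pairs go beyond this bias was not tested, so a preferred arrangement of pairs stays open. Close copies of an inverted repeat at most pairs are argued against by a median identity of 35% next to the paired sites (35 to 40). It covers 20 bases matched without gaps and lay below a bar set after the result was seen. The identity was slightly above the 30% between peaks. Diverged or gapped copies, or copies at some pairs only, could not be detected this way.

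The second pattern was the ribosomal protein genes. Strong transcription in general stays open: of tRNA genes 2.76% (8 of 290, 1.40 to 5.35) had a summit within 500 bp, but another polymerase transcribes them, so the low share, first read as a bound against this explanation, excludes nothing. Housekeeping promoters in general are argued against by the share of genes with a summit, 16.7% (12.3 to 22.2) in the 5 families together. This holds for the share only, since some of these families had stronger top peaks than the ribosomal protein genes. A neighbouring gene is argued against because ribosomal protein genes had the nearest TSS to a summit at 57.6% (Fisher's exact p 5.1e-20). Enrichment unrelated to Oaz at very active promoters stays open, since other tagged proteins and the control were not analysed here.

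The third pattern was the peak cluster at Oaz. Extra copies of the locus in the transgenic strain cannot be told apart from binding there, because candidate peaks past no threshold had a median signal 1.24 times that of like windows (1.16 to 1.56, n = 69), an interval that spans the bound set for it, a reading settled after the value was seen. The locus median of 25.7 also lay above the 95th percentile of like windows (24.6), as extra copies would give. Binding through ACAGTG is also open, since 6.25% of the 16 summits held it (1.11 to 28.3), too few to tell.

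A separate hypothesis was that promoter peaks prefer divergent genes. Of 1152 genes named by a promoter peak, 52.4% (49.5 to 55.3) had an opposite-strand TSS within 1000 bp upstream, against 34.7% of other genes (Fisher's exact p 6.72e-32). The value is consistent with a preference for shared promoters, and gene spacing was not held constant.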
